A study of Zonotrichia albicollis with 38 samples.

How the data were processed

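RNA-seq libraries were analysed from 19 male white-throated sparrows (Zonotrichia albicollis), a songbird with a white-striped (WS) and a tan-striped (TS) morph. WS birds carry ZAL2m, an inverted form of chromosome ZAL2, which TS birds lack. There were 10 WS and 9 TS birds, and each gave 1 hypothalamic (HYP) and 1 medial amygdala (MeA) library, 38 in all. Per the labels, the free-living birds were taken in the season of territorial behaviour on the day after a staged intrusion. Brains were frozen and sectioned, and each region was taken with a punch tool. HYP punches held the caudal preoptic area, the paraventricular nucleus, the anterior hypothalamus and the ventromedial hypothalamus. MeA made up most, and not all, of the tissue of the MeA samples. RNA was extracted with a Qiagen AllPrep kit and libraries were made with Illumina's TruSeq RNA kit v2, per the labels' protocols.

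The authors deposited 3 tables. The first holds read counts per gene and library, whole numbers that are not normalized. The name of this table in the labels mentions ZAL2m, but how ZAL2m sequence entered the alignment is not given in the sources used here. The other tables, 1 per region, hold values that the authors had variance-stabilized, on an approximately log2 scale. These deposited log2-scale values were used in the alternative fits only. They list 13605 genes in HYP and 13426 in MeA, each with at least 10 counts over the region's libraries. Among all genes counted, 13820 and 13691 reached that number, so the rule that removed the rest is not known. Within each library the deposited values ranked genes in the order of their log2 CPM (counts scaled to the library total), with a Spearman correlation of 1. Per the submitters' processing notes the tools were Novoalign, SAMtools, GATK, STAR, HTSeq and DESeq2, with no version, role or order. The genome build, the treatment of reads that match several genes and the use of strand are not given in the sources used here. Counts of overlapping, antisense or near-identical genes may therefore hold reads of a partner. The count table has 2 columns of a bird with no sample among those listed, and these columns were not used.

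Library totals ran from 7150476 to 14482856 counts. Libraries of the same group differed by far more than sampling noise, with a chi-square per degree of freedom of 5.39 to 37.4 over all pairs within groups, so no library was counted as a repeat of another. Replicates are birds, named by the band number in the titles (Sample_ and the number). The same number marks both regions of a bird, and this pairing was checked on 8925 genes. The deviations of each library from its group mean correlated best with the other region of the same bird in 19 of 19 birds, with r of 0.28 to 0.546 for the own bird against a highest value of 0.226 for any other.

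Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter and the quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. WS was compared with TS within each region with morph alone in the model. HYP against MeA and the morph by region interaction were fitted on all 38 libraries with the bird as a block. The age classes SY and ASY were compared within each region with morph in the model. The default of glmQLFit was kept after the counts with its robust option had been seen, and that option was added to the alternatives. Means and SDs are of CPM on TMM-scaled library sizes, scaled within each region. Folds are the fitted log2 fold changes put back on the linear scale, so they can differ from ratios of the printed CPM. Log2 fold changes come from the edgeR fits. Each standard error (SE) was derived from the fit, as the absolute log2 fold change over the square root of its F statistic.

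Genes were placed on chromosomes with a gene table of the assembly bZonAlb1.hap1. Because the authors' build is not known, positions served only to tell which genes share a chromosome or neighbour each other. Of 15111 genes counted, 12532 were placed, 9559 by symbol and 2973 by gene ID, and 2579 were not matched. The gene table also gave a symbol to 1534 of 4637 identifiers that began with LOC. The chromosome of the inversion was taken as the one that holds most of 230 anchor genes, chosen for their place on the matching chicken chromosome. It held 218 of the 219 anchor genes that could be placed and 1016 genes of the count table. It is called ZAL2 in the text, and it includes genes that may lie outside the inversion. Calls on ZAL2 and elsewhere were compared with a two-sided Fisher's exact test over tested genes with a position. Its p-values and intervals take genes as independent, though all were measured in the same birds, so they do not cover the spread among birds.

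Besides the anchor genes, 20 lists were tested, so 21 in all: steroid receptors and steroidogenesis, neuropeptides, neuropeptide receptors, monoamine genes, GABA and glutamate signalling, immediate early genes, interferon and innate immune genes, clock genes, photoperiod and thyroid hormone genes, heat shock genes, and markers of astrocytes, oligodendrocytes, microglia, endothelial and mural cells, ependyma and choroid plexus, erythrocytes, anterior pituitary, hypothalamus, pallium and neurons. Lists with at least 3 tested members went into camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Repeats used an estimated correlation and fry.

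Genes named in the morph comparisons were, among called genes with a symbol and a mean of at least 1 CPM, the 8 with the largest and the 8 with the lowest log2 fold change. Up to 4 called members of each list other than the anchor genes, by adjusted p, were added, as were ESR1 and VIP whatever their result. Between regions the rule took 5 genes in each direction and up to 4 called members of each list, and for the interaction the 8 smallest adjusted p. Some genes that the rule names are not reported here. Any other gene named was chosen after its values were seen, and the text says so.

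The procedure was tested on simulated counts with 200 changed genes among the 11930 tested in HYP and the 11672 tested in MeA. Counts were drawn independently for each gene and library, without correlation between genes and without effects of bird or region. The shares below hold for such counts, and the real libraries may give more false calls and fewer recovered genes. For WS against TS in HYP the test recovered 54% of genes changed 1.3-fold, 78% of those changed 1.5-fold and 98% of those changed 2-fold, and 4.09% of its calls were false. For WS against TS in MeA the shares were 58%, 78% and 92%, with 4.12% false calls. For ASY against SY the test recovered 88% of genes changed 2-fold in HYP and 82% in MeA. Over the 12245 genes tested in both regions together it recovered 86% of 2-fold changes for the interaction and 98% for HYP against MeA.

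Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter at a mean of 5 CPM, age class or stage as a covariate, the birds of stage E alone, limma on the deposited log2-scale values, limma-voom, fits without the bird block or with the bird as a random effect, and each bird left out in turn. The meanings of the stage codes and of SY and ASY are not given in the labels. The title of the series links genes of the inversion to territorial song, and song measurements were not analysed here.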

Results

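The series asked how gene expression in the HYP and the MeA differs between the morphs of the white-throated sparrow, which differ by an inversion of chromosome ZAL2. Expression was measured by RNA-seq in both regions of 10 WS and 9 TS males collected in the territorial season. Library totals ran from 7150476 to 12441525 counts in HYP of WS birds, from 8653109 to 12394806 in HYP of TS birds, from 7342059 to 14482856 in MeA of WS birds and from 8361042 to 12442047 in MeA of TS birds. Age class was uneven between the morphs, with 7 of 9 TS birds labelled SY and 8 of 10 WS birds labelled ASY. Stage was labelled E in 6 TS and 8 WS birds.

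In HYP the morphs differed in 95 of 11930 genes tested, 56 higher and 39 lower in WS, and 7 differed by over 2-fold, all higher in WS. EPM2A, which encodes the glycogen phosphatase laforin, stood at 55.2 ± 5.42 CPM in WS and 30.4 ± 2.33 CPM in TS (SD, n = 10 and 9), a log2 fold change of 0.86 with an SE of 0.060 (edgeR adjusted p = 2.67e-09). NTPCR, a nucleoside triphosphatase, showed the opposite difference, with 34.6 ± 2.53 CPM in WS and 59.3 ± 3.16 CPM in TS (log2 fold change −0.77, SE 0.046, edgeR adjusted p = 2.56e-10). RRP36, a factor of ribosomal RNA processing, was lower in WS with the same adjusted p (log2 fold change −0.70). For all of these genes every WS library lay outside the range of the TS libraries. Such a separation of the morphs was found for 34 genes in HYP, each of them called, where chance gives it to 0.0022% of genes, or 0.26 genes here.

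Other genes higher in WS in HYP included the kinetochore gene CENPF, at 4.17 ± 0.919 against 1.35 ± 0.428 CPM (log2 fold change 1.63, SE 0.18, edgeR adjusted p = 4.93e-06). CEP57L1, a relative of a centrosomal protein, differed by 1.17 on the log2 scale. ACSS1, the mitochondrial acetyl-CoA synthetase, differed by 1.06 and TCTE1, a gene of the axonemal dynein regulatory complex, by 1.09. The kindlin gene FERMT1, the kinesin gene KIF25 and the syntrophin gene SNTG2 had log2 fold changes of 0.71, 0.69 and 0.75. All 10 WS libraries lay above the TS mean for each of these genes.

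Genes lower in WS in HYP included CMPK2, an interferon-induced mitochondrial nucleotide kinase, at 7.78 ± 1.34 against 15.5 ± 2.18 CPM (log2 fold change −0.99, SE 0.10, edgeR adjusted p = 2.33e-06). The Src-family kinase gene FRK (−0.97), the kinetochore-binding gene KNSTRN (−0.94), the vesicle-tethering gene TRAPPC3L (−0.81), the calcium homeostasis modulator gene FAM26E (−0.79) and LTBP1, which binds latent TGF-beta (−0.66), were also lower by these log2 fold changes. ESR1, the estrogen receptor alpha gene, did not pass the test in HYP, with 17.2 ± 2.84 CPM in WS and 18.6 ± 4.41 CPM in TS (log2 fold change −0.12, SE 0.13, edgeR adjusted p = 0.893). The neuropeptide gene VIP did not pass either, with 74.6 ± 17.1 and 67.8 ± 29.2 CPM (log2 fold change 0.13, SE 0.18, edgeR adjusted p = 0.934). With age class as a covariate 51 genes were called in HYP, and 45 among the birds of stage E alone. TCTE1 and KNSTRN lost their calls in several of the other fits, among them those with age class or stage as a covariate, ACSS1 and SNTG2 with age class, and KIF25 and FRK among the birds of stage E alone.

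In MeA the morphs differed in 61 of 11672 genes tested, 36 higher and 25 lower in WS, and 12 differed by over 2-fold. CEP57L1 was at 2.81 ± 0.586 CPM in WS and 0.675 ± 0.183 CPM in TS (SD, n = 10 and 9; log2 fold change 2.06, SE 0.18, edgeR adjusted p = 1.11e-06). CD109, which encodes a membrane-anchored protein that binds TGF-beta, was at 14.2 ± 6.08 against 4.85 ± 0.868 CPM (log2 fold change 1.56, SE 0.21, edgeR adjusted p = 0.000199). ESR1 was higher in WS, at 1.33 ± 0.366 against 0.508 ± 0.245 CPM (log2 fold change 1.36, SE 0.25, edgeR adjusted p = 0.00755), and 10 of 10 WS libraries lay above the TS mean. This was a low level, with 186 counts of ESR1 over the 19 MeA libraries.

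Further genes higher in WS in MeA were RRM2, a subunit of ribonucleotide reductase (log2 fold change 1.48), CENPF (1.43), the chemokine receptor gene CCR6 (1.25), FNDC1, which holds fibronectin repeats (1.12), the blood cell gene PLEK (1.00) and the small membrane protein gene SMIM8 (0.77). NTPCR was again lower in WS, at 24.5 ± 1.43 against 39.6 ± 3.45 CPM (log2 fold change −0.69, SE 0.055, edgeR adjusted p = 3.04e-07), as was RRP36 (−0.53). The potassium channel gene KCNK5 (−0.78), the scaffold gene DISC1 (−0.64, listed as LOC102072414), FAM150B, which encodes a ligand of the ALK receptor (−0.57), the ankyrin-repeat gene ANKEF1 (−0.51), TAF5L of a histone acetylase complex (−0.51) and the mitochondrial transporter gene ABCB10 (−0.49) were lower as well. PLEK lost its call in 13 of 19 fits with 1 bird left out (adjusted p up to 0.111, without bird Sample_23599) and KCNK5 in 3 (up to 0.057, without bird Sample_23608); over all alternatives their adjusted p ran from 0.0202 to 0.492 and from 0.000953 to 0.16. CCR6, FNDC1, PLEK, KCNK5, DISC1 and ANKEF1 lost theirs with age class as a covariate, and these and RRM2, RRP36 and ABCB10 among the birds of stage E alone. VIP did not pass the test, with 60.9 ± 15.5 and 66 ± 9.62 CPM (log2 fold change −0.11, SE 0.13, edgeR adjusted p = 0.822). The morphs did not overlap in 24 genes, all called, where 0.25 would be given by chance. In MeA 118 genes were called by DESeq2, 18 with age class as a covariate, 16 among the birds of stage E alone and 35 without 4 libraries at the ends of the main axis of variation, an alternative chosen after that axis was seen. CCR6, PLEK, KCNK5, DISC1 and ANKEF1 lost their calls without these 4 libraries (edgeR adjusted p from 0.0552 for CCR6 to 0.4165 for PLEK). The call of ESR1 ended with age class as a covariate (log2 fold change 1.27, SE 0.30, adjusted p = 0.117), among the birds of stage E alone (1.36, adjusted p = 0.166) and without those 4 libraries (1.35, adjusted p = 0.0718); over all its alternatives the adjusted p ran from 0.00171 to 0.166.

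**Figure D1:**
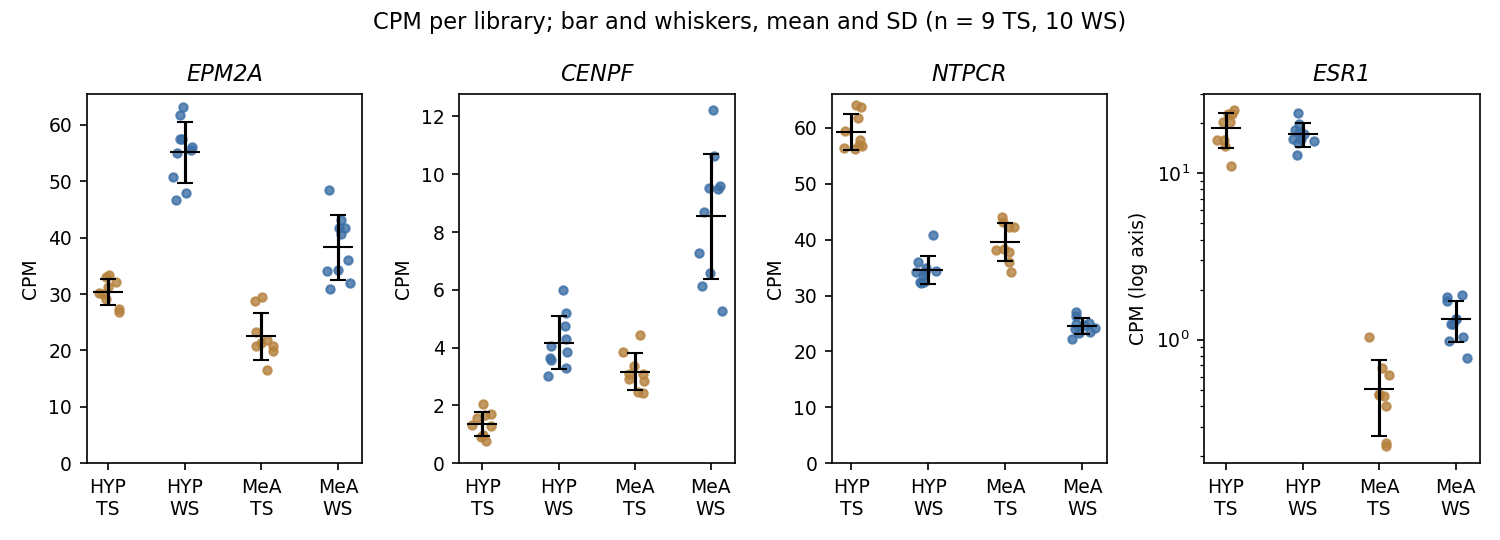
CPM of EPM2A, CENPF, NTPCR and ESR1 in each of the 38 libraries, by region and morph, with the mean as a bar and whiskers of 1 SD (9 TS and 10 WS birds); the axis of ESR1 is logarithmic. EPM2A and CENPF lie higher and NTPCR lower in WS in both regions, while ESR1 has means of 1.33 CPM in WS and 0.508 CPM in TS in MeA and of 17.2 and 18.6 CPM in HYP.

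Most of the genes called between the morphs lay on ZAL2. In HYP 82 of 875 tested ZAL2 genes were called (9.37%) and 4 of 9750 genes placed elsewhere (0.041%), an odds ratio of 251.7 with a 95% interval of 94.2 to 931 (Fisher's exact test, two-sided, p = 5.16e-85). In MeA 53 of 849 ZAL2 genes (6.24%) and 1 of 9570 other genes (0.01%) were called, an odds ratio of 633.4 with an interval of 109 to 16400 (p = 2.11e-57). With so few calls elsewhere the odds ratios moved widely: with 1 bird left out from 208.7 (without bird Sample_23608) to 964.7 (without bird Sample_23610) in HYP, and infinite without bird Sample_23540 or Sample_23623, and in MeA from 242.4 (without bird Sample_23623) to 657.3, and infinite where no gene elsewhere was called, while DESeq2 gave 91.04 and 117.6. With age class as a covariate 45 ZAL2 genes and 3 others were called in HYP (odds ratio 176, interval 56.3 to 903), and 15 and 0 in MeA (lower bound 41). A further 9 calls in HYP and 7 in MeA had no position. The 5 calls placed elsewhere are named here after their values were seen, except KNSTRN: they were EPS15L1 (log2 fold change 0.32), CAV2 (−0.37), RASA2 (0.22) and KNSTRN in HYP, and CHST13 (0.31) in MeA. Unadjusted p lay under 0.05 in 34.7% of ZAL2 genes and 5.41% of other genes in HYP, and in 31.9% and 6.9% in MeA. Of the ZAL2 calls in HYP 50 were higher and 32 lower in WS, and of those in MeA 32 were higher and 21 lower. With age class as a covariate the split was nearer to even, with 23 higher and 22 lower in HYP and 8 higher and 7 lower in MeA.

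Among 11434 genes tested in both regions, 89 were called in HYP and 57 in MeA. Both calls fell on 32 genes, and all 32 had the same direction, with 19 higher and 13 lower in WS. Independent lists spread evenly over all genes would give 0.444. That baseline is too low, because most calls in both regions lay on ZAL2, as did 29 of the shared genes. An expectation within ZAL2 was not computed. Both regions came from the same birds, so the lists are not independent. In 99 other assignments of the morphs to the birds 0 genes were called in both regions, but such assignments, drawn separately for each region, called at most 28 genes in HYP and 2 in MeA and mostly none, so this says little about what the shared birds add to the overlap. Across 838 ZAL2 genes, which are not independent replicates, the log2 fold changes of HYP and MeA had a Pearson correlation of 0.682 and a Spearman correlation of 0.531. The same 99 assignments gave Pearson values of 0.200 to 0.669 with a median of 0.454 (permutation p = 0.01, the smallest that 100 assignments can give). The covariance was 0.0469 against a median of 0.00715 and a highest value of 0.0241. Across 9380 genes on other chromosomes the Pearson correlation was 0.297, below the median of 0.363 of the other assignments (permutation p = 0.84), with a covariance of 0.0052 against a median of 0.00589.

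**Figure D2:**
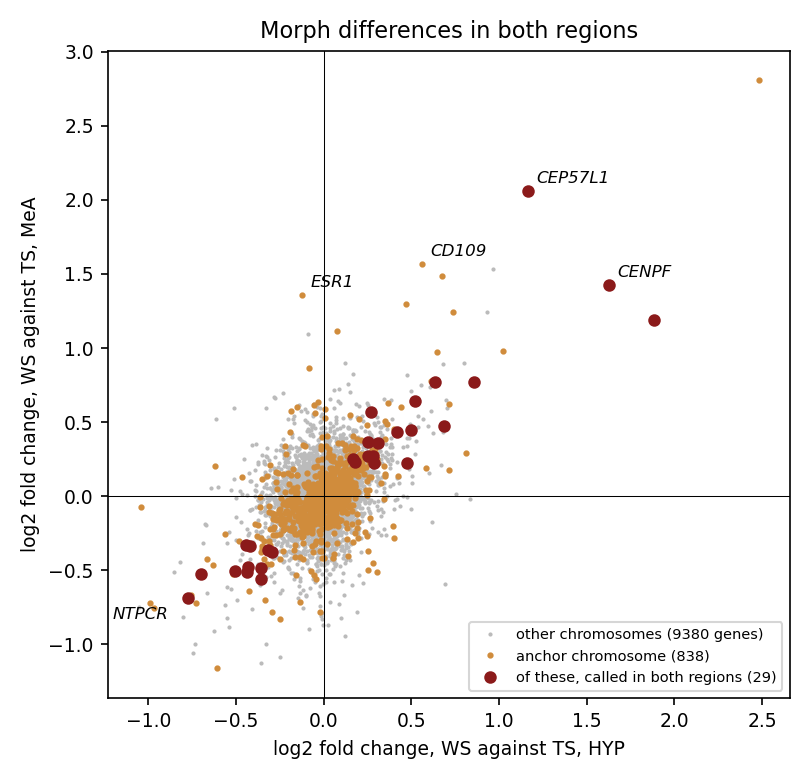
Log2 fold change of WS against TS in HYP (horizontal axis) and MeA (vertical axis) for 9380 genes of other chromosomes in grey and 838 ZAL2 genes in orange, with 29 ZAL2 genes called in both regions in red. These 29 lie in the quadrants where both regions differ in the same direction, while ESR1 lies near 0 in HYP and at 1.36 in MeA.

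The difference between the morphs itself differed between the regions for 3 of 12245 genes, all on ZAL2 and all with a higher log2 fold change of WS against TS in MeA. BTBD3, known to direct the growth of dendrites, was higher in WS in MeA by 0.40 on the log2 scale and had a value of −0.01 in HYP (difference −0.41, SE 0.054, edgeR adjusted p = 0.0012). For CD109 the values were 1.56 in MeA and 0.56 in HYP (difference −0.97, SE 0.14, edgeR adjusted p = 0.00485). ESR1 had 1.36 in MeA and −0.12 in HYP (difference −1.49, SE 0.26, edgeR adjusted p = 0.039). DESeq2 called 17 genes, 7 of them with a positive difference. ESR1 lost this call in 14 of 19 fits with 1 bird left out, with the highest adjusted p of 0.14 without bird Sample_23711, and CD109 lost it without the bird block (adjusted p = 0.613, the highest over its alternatives, with 1.67e-05 the lowest). In limma-voom with the bird as a random effect both CD109 (adjusted p = 0.0885) and ESR1 (adjusted p = 0.169) lost it.

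No list passed camera between the morphs, in HYP over 21 lists (lowest adjusted p 0.433) or in MeA over 20 (lowest adjusted p 0.203). Camera tests a shift of a list in 1 direction. In fry's test for changes in either direction the anchor genes passed in both regions (adjusted p = 2.56e-32 in HYP and 4.41e-09 in MeA). Interferon genes in HYP (fry adjusted p = 2.49e-08) and steroid genes in MeA (0.0487) passed too, and no other list did. Fry does not compare a list with other genes. Of the ZAL2 anchor genes 15 were higher and 6 lower in WS among 215 tested in HYP, and 62 passed when adjusted over the list alone. In MeA 6 were higher and 1 lower among 209, and 41 passed when adjusted over the list alone. Of the other lists, interferon and innate immune genes held 1 called gene in HYP, CMPK2, and steroid receptors and steroidogenesis 1 in MeA, ESR1. No other list held a called gene in the region in question. Adjusted over the list alone, 1 gene each passed among the immediate early genes in HYP and among the interferon genes and the GABA and glutamate genes in MeA. The signs of a list's median, mean and test differed for the anchor, monoamine and immediate early genes in HYP and for neuropeptide receptors, photoperiod genes and endothelial markers in MeA. With age class as a covariate the interferon list passed in MeA (median log2 fold change without that covariate 0.33, adjusted p = 0.0145), as did the anchor genes towards lower values (adjusted p = 0.0487). Neither call held with an estimated correlation in that fit (adjusted p = 0.87 with an estimated correlation for both lists).

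The regions differed far more than the morphs. With the bird as a block, 9772 of 12245 genes differed between HYP and MeA, 5000 higher and 4772 lower in HYP, and 2131 of them by over 2-fold. The hypothalamic transcription factor genes FEZF1 and ISL1 were at 66 ± 13.5 and 78.7 ± 12.2 CPM in HYP (SD, n = 19) and at 0.105 ± 0.0939 and 0.134 ± 0.107 CPM in MeA, with log2 fold changes of 8.92 (SE 0.11) and 8.88 (SE 0.11) and the same edgeR adjusted p of 3.28e-26. NPVF, the precursor gene of gonadotropin-inhibitory hormone, was at 694 ± 246 against 1.45 ± 0.61 CPM (log2 fold change 8.68). The transcription factor gene PRDM12 had a log2 fold change of 7.76. In MeA the complexin gene CPLX3 was 302.5-fold higher than in HYP, at 139 ± 45 against 0.497 ± 0.249 CPM, and the kinase gene DYRK4 194.5-fold, at 234 ± 58.9 against 1.3 ± 0.637 CPM. The genes of secreted proteins ITIH2 and SPP2 were 146.8-fold and 123.6-fold higher in MeA. ATOH7, a proneural transcription factor gene, had 449 counts in MeA and 1 in HYP, a ratio of 466 with a counting interval of 83.2 to 18400, which covers counting error only. The MeA libraries varied widely in it, at 2.43 ± 4.25 CPM, and bird Sample_23710 held 171 of the 449 counts. Without this bird the ratio was 288, with an interval of 51.2 to 11400. Bird Sample_23705 held the 1 count in HYP, and without it the ratio has no value. Each of these genes differed in the same direction in 19 of 19 birds.

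Markers of the hypothalamus were higher in HYP in 11 of 12 tested members and lower in 1, LHX6 (median log2 fold change 5.19, camera adjusted p = 1.13e-05). HMX2 was 202.1-fold and OTP 160.9-fold higher. Neuropeptide genes were higher in 13 of 16 and lower in 1, NTS (median 3.22, adjusted p = 0.000189). The galanin gene GAL stood at 590 ± 117 CPM in HYP and 5.08 ± 3.53 CPM in MeA, the prodynorphin gene PDYN at 519 ± 171 and 11.2 ± 3.44 CPM and the proenkephalin gene PENK at 1439 ± 244.3 and 91.9 ± 25.3 CPM. Markers of the pallium were lower in HYP in 10 of 12 and higher in 1 (median −2.36, adjusted p = 0.000189), with ETV1 7.95-fold, ZBTB18 6.86-fold and NEUROD1 41.04-fold higher in MeA. These 3 lists also passed with an estimated correlation, with adjusted p of 0.00268, 0.0185 and 0.0185.

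Another 9 lists passed with the preset correlation and not with an estimated one. Neuropeptide receptor genes were higher in HYP in 15 of 21 and lower in 5, with the melanocortin receptor genes MC3R and MC4R 44.09-fold and 10.49-fold and the mu opioid receptor gene OPRM1 4.93-fold higher (adjusted p = 0.0633 with an estimated correlation). Genes of GABA and glutamate signalling were lower in HYP in 18 of 29 and higher in 8 (adjusted p = 0.391 with an estimated correlation), among them the glutamate receptor genes GRIA3, with a log2 fold change of −1.84, and GRIA2, with −1.32. Immediate early genes, which respond to neuronal activity, were lower in HYP in 7 of 9 and higher in 2, with FOSL2 8.40-fold and NR4A3 7.75-fold higher in MeA (adjusted p = 0.391 with an estimated correlation). Heat shock and chaperone genes were higher in 14 of 18 and lower in 1 (median 0.18, adjusted p = 0.457 with an estimated correlation), BAG3 by 1.67 on the log2 scale, and the member lower in HYP was FKBP5, a co-chaperone of the glucocorticoid receptor (−1.69).

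The lists of other cell types that passed were all lower in HYP. Markers of oligodendrocytes and myelin were lower in 8 of 8 (MBP 2.87-fold higher in MeA, adjusted p = 0.391 with an estimated correlation) and microglial markers in 8 of 8 (LY86 8.42-fold, adjusted p = 0.146 with an estimated correlation). Astrocyte markers were lower in 6 of 8 and higher in 1 (SLC1A2 2.13-fold higher in MeA, adjusted p = 0.391 with an estimated correlation). Endothelial and mural markers were lower in 9 of 11 and higher in 1 (ACTA2 2.41-fold, adjusted p = 0.391 with an estimated correlation). Erythrocyte markers were lower in 5 of 5 (RHAG 7.03-fold, adjusted p = 0.391 with an estimated correlation), and their levels varied widely among MeA libraries, with 11.7 ± 8.57 CPM for RHAG against 1.65 ± 0.782 CPM in HYP. ITIH2, among the genes with the highest folds towards MeA, varied likewise, at 23.7 ± 17.9 CPM.

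The remaining 9 lists did not pass, although many of their members differed. Of 14 genes of steroid signalling 9 were higher and 5 lower in HYP (camera adjusted p = 0.308), with the progesterone receptor gene PGR 73.9-fold and ESR1 16.72-fold higher. Of 26 monoamine genes 14 were higher and 8 lower (adjusted p = 0.397), with DDC, which makes dopamine and serotonin from their precursors, 146.8-fold higher in HYP and the serotonin receptor gene HTR1D 31.68-fold higher in MeA. Photoperiod and thyroid hormone genes were higher in 6 and lower in 3 of 10 (adjusted p = 0.18), with CRYM, which binds thyroid hormone, 23.88-fold and the deiodinase gene DIO3 9.77-fold higher. Clock genes were higher in 3 and lower in 9 of 15 (0.098), and interferon genes higher in 1 and lower in 7 of 12 (0.189). Markers of ependyma and choroid plexus were higher in 5 and lower in 2 of 9 (0.279), with the cilium gene FOXJ1 20.35-fold higher in HYP and the water channel gene AQP1 9.93-fold higher in MeA. Pituitary markers were higher in 3 of 4 (0.0688), neuronal markers higher in 6 and lower in 6 of 12 (0.875) and the ZAL2 anchor genes higher in 82 and lower in 94 of 215 (0.477). For neuronal markers the median, 0.06, was above 0 while the mean and the test pointed lower, and for the anchor genes the mean, 0.03, was above 0 while the median and the test pointed lower.

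**Figure D3:**
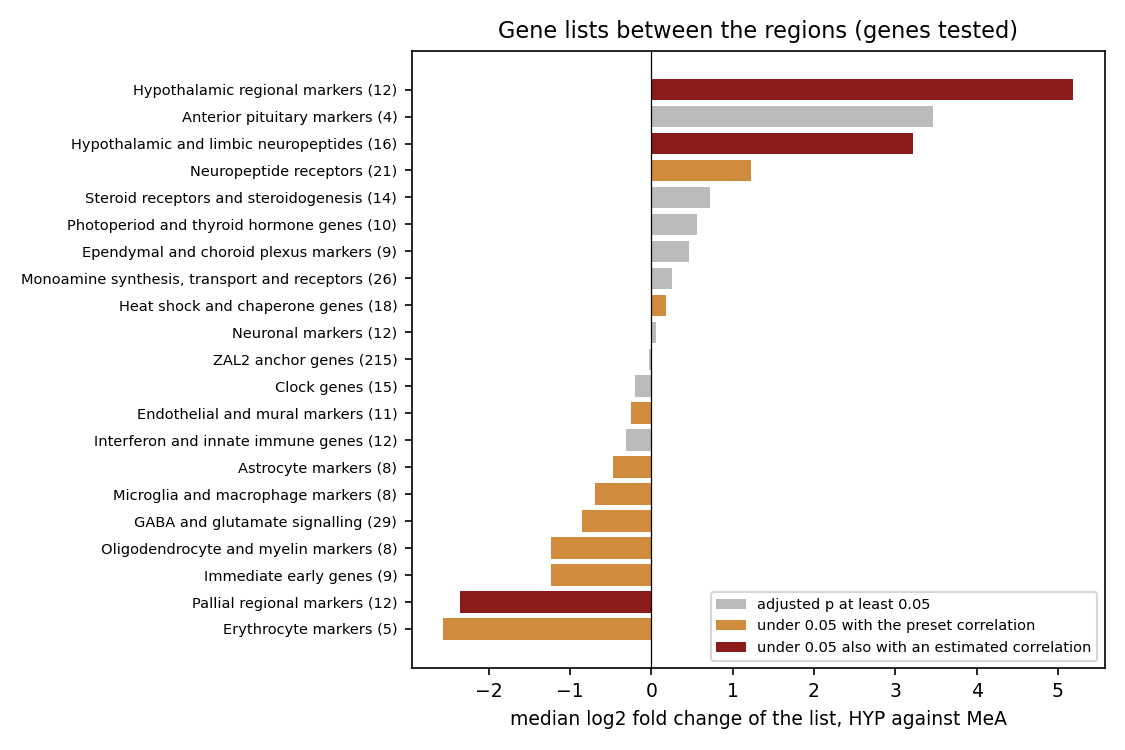
Median log2 fold change of HYP against MeA for each of 21 gene lists, with the number of genes tested in brackets; bar colour gives the camera result. Markers of the hypothalamus, neuropeptides and markers of the pallium are the lists that passed with both correlations, with medians of 5.19, 3.22 and −2.36.

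Between the age classes, with morph in the model, edgeR called 0 of 11930 genes in HYP and 0 of 11672 in MeA. Unadjusted p lay under 0.05 for 562 and 418 genes, where 596.5 and 583.6 would be given by chance. DESeq2 called 1 gene in HYP and 0 in MeA, and edgeR without the low-count filter called 1 in HYP. In data simulated for this comparison, 58% of genes changed 1.3-fold and 68% of those changed 1.5-fold were called in HYP, and 34% and 62% in MeA.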

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

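Of the tests on ESR1 below, the one of hypothalamic tissue and the t interval for age class were chosen after the result was seen.

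Single libraries stood apart from the rest of their group in 12 of 208 groups examined, where chance gives about 1 in 20, or 10.4. In HYP of WS birds these were bird Sample_23596 for FERMT1 (12.4 CPM, the others 7.45 to 9.48), bird Sample_23625 for FRK (3.38 CPM, the others 1.05 to 1.92), bird Sample_23602 for NTPCR (40.9 CPM, the others 32.2 to 35.9) and bird Sample_23604 for the mean score of the immediate early genes (−0.696, the others −0.121 to 0.423). In HYP of TS birds, bird Sample_23615 stood apart in KIF25 (23.7 CPM, the others 10.5 to 16.3), CCR6 (3.19 CPM, the others 0.524 to 1.62) and TAF5L (69.4 CPM, the others 51.2 to 60.3), and bird Sample_23626 in KNSTRN (0.824 CPM, the others 1.3 to 1.78). In MeA of WS birds, bird Sample_23604 was high in ACSS1 (1.6 CPM, the others 0.682 to 1.16) and FNDC1 (13.4 CPM, the others 4.36 to 8.33). In MeA of TS birds, bird Sample_23608 was low in SNTG2 (0.114 CPM, the others 0.556 to 0.96) and bird Sample_23711 high in DISC1 (18.5 CPM, the others 8.25 to 11.5).

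The morph difference differed between the regions, by the interaction test, for BTBD3 (−0.415 on the log2 scale, HYP minus MeA), CD109 (−0.968) and ESR1 (−1.49). Among 100 assignments of the morphs to the birds, 3 gave at least as many calls as the real one, which gave 3. That share is under 0.05, but the 2 other assignments gave 40 and 20 calls. A structure among the samples that these groups do not describe could give such counts, and this was not tested. The count therefore argues against chance only by its share and does not set the 3 genes firmly apart from it, and ESR1 and CD109 each lost this call in other fits.

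ESR1 was higher in WS than in TS in MeA, and hypothalamic tissue in the MeA punches of WS birds would raise it, since ESR1 is 16.72-fold higher in HYP. The test used 9 genes that are at least 32-fold higher in HYP and passed the low-count filter in MeA. Genes with such folds that fell below that filter were not used. The needed share of tissue, 4.76%, would raise the 9 genes by a median of 1.88 on the log2 scale. Their median was 0.261 (95% bootstrap interval −0.114 to 0.614) and 0 of them passed edgeR's test. This argues against tissue like the HYP punches and not against another neighbouring area. A single library is argued against as well, because the adjusted p without any 1 bird was at most 0.0203. Whether age class is the source of most of the difference cannot be decided. With it as a covariate the log2 fold change was 1.27 (SE 0.30) against 1.36 (SE 0.25) without it, or 93.7%. The normal 95% interval of 0.689 to 1.86 lay above 0.679, the bound set beforehand. The lower end of the t interval, 0.641, did not, so the outcome depends on the interval used. The call ended in that fit (edgeR adjusted p = 0.117), where the SE rose and the fold hardly moved. The adjusted p also depends on the other genes tested, and the cause of the lost call was not tested. A difference between the morphs in the expression of ESR1 in MeA remains a hypothesis, with age class and tissue of another neighbouring area both open.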

How the results depend on the processing

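The fits with robust dispersion estimates and with the leptomeningeal score, the list test with age class and an estimated correlation together, and the fit without the 4 MeA libraries at the ends of the first principal component (birds Sample_23600, Sample_23602, Sample_23615 and Sample_23626) were chosen after the data were seen. The 95 calls in HYP became 51 (26 higher, 25 lower) with age class as a covariate and 45 among the birds of stage E alone, and the other settings gave 84 to 140. Of the 51 and the 45, 47 and 43 were among the 95. The 61 calls in MeA became 118 with DESeq2, which included all 61, and 18 with age class (17 shared), 16 in stage E alone (15 shared) and 35 without the 4 libraries (32 shared). Stage E alone left 6 TS and 8 WS birds, and age class is uneven between the morphs, so both fits have less power; how much of the loss comes from that was not tested. The interaction gave 17 calls with DESeq2 against 3, and 4 with the bird as a random effect, 1 of them shared. ASY against SY in HYP gave 1 call with DESeq2 and 1 without the low-count filter against 0; in MeA all settings gave 0. With age class, 2 lists passed in MeA against 0, and 0 with age class and an estimated correlation. Between the regions 3 lists passed with an estimated correlation and 21 with fry, which does not compare a list with other genes, against 12. The cause of these changes was not tested.

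The band numbers pair the regions of each bird. Without the replicate block the interaction gave 2 calls, with CD109 lost, and HYP against MeA 9234 against 9772. With 1 bird left out, the counts ran from 73 to 92 in HYP, 48 to 61 in MeA, 2 to 4 for the interaction, 9676 to 9754 between the regions and 0 to 0 for age class in both regions. The odds ratio for ZAL2 ran from 208.7 to 964.7 in HYP and 242.4 to 657.3 in MeA, where it was finite. It was infinite, because no gene elsewhere was called, at a threshold of 0.01 in both regions, with age class as a covariate in MeA, and in some fits with 1 bird left out. The correlation between regions ran from 0.655 to 0.7 for ZAL2 genes and 0.274 to 0.336 for others. With DESeq2 the odds ratios were 91.04 and 117.6.

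No named gene, no correlation and no list past its threshold turned its direction under the alternatives run. Of the lists that did not pass, those of steroid, immediate early, heat shock and microglial genes in HYP and of neuropeptide receptors, photoperiod genes and endothelial markers in MeA did so with age class, again without passing. Each named gene or list was counted once per setting, so that a gene can count several times, and the fits with 1 bird left out entered only by those with a gene's smallest and largest change: the call was lost in 13 such pairs in HYP, 30 in MeA, 4 for the interaction and 9 between the regions, and the side of the threshold was the same in 196, 216, 23 and 689. All 9 between the regions were lists tested with an estimated correlation, and no named gene lost its call there. Over all fits with 1 bird left out, calls were lost for TCTE1 (11 of 19 fits, adjusted p up to 0.0717 without bird Sample_23607), KNSTRN (15 fits, 0.0982 without bird Sample_23607), PLEK (13 fits, 0.111 without bird Sample_23599), KCNK5 (3 fits, 0.057 without bird Sample_23608) and the interaction of ESR1 (14 fits, 0.14 without bird Sample_23711). Genes near 1 CPM, such as TCTE1, KNSTRN and ESR1 in MeA, rest on few counts per library.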

Other observations

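Of the tests below, the 3 on the concentration of calls on ZAL2, the one of the leptomeningeal score between the morphs and the one of clock phase were chosen after the result was seen.

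Birds differed widely in the levels of clock genes and in step between the regions. ARNTL, an activator of the circadian clock, ran from 15.4 to 60.2 CPM in HYP and 13.5 to 55.1 CPM in MeA, and PER3, a gene of its feedback arm, from 21 to 146 and 21 to 129 CPM. Over 19 birds ARNTL and PER3 were inversely related in HYP (Pearson r −0.97, Spearman rho −0.942) and in MeA (−0.949 and −0.958), and ARNTL in HYP went with ARNTL in MeA of the same bird (0.963 and 0.93). All 3 relations computed had a permutation p of 1e-05, also when adjusted, which is the smallest that the permutations can give. Without the 2 birds farthest from the median r was −0.972, −0.97 and 0.963, and within the morphs it ran from −0.941 to −0.996 for ARNTL with PER3 and was 0.962 and 0.987 between the regions. A candidate explanation is that birds were collected at different clock phases; the positive r of 0.963 between regions and the inverse relations are what it needs, but collection times were not analysed here.

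GREB1, an estrogen-responsive gene on ZAL2 that was picked after its values were seen, was higher in WS in HYP, at 106.7 ± 27.1 against 68.3 ± 15.8 CPM (log2 fold change 0.64, SE 0.15, edgeR adjusted p = 0.0303). In MeA it stood at 2.18 ± 1.17 against 1.1 ± 0.324 CPM and did not pass the test (log2 fold change 0.97, SE 0.28, edgeR adjusted p = 0.198).

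The concentration of morph differences on ZAL2 was weighed against the alignment of reads and age class. Poorer alignment of ZAL2m reads would lower genes in WS. By its direction it does not give the calls higher in WS, whatever their share, so that share decides nothing about it. At least 60.4% of the ZAL2 calls in each region were higher in WS (95% intervals 49.6 to 71.6% in HYP and 46 to 73.5% in MeA, which take genes as independent). With age class as a covariate the share was 51.1% and 53.3% of fewer calls. For the calls lower in WS poorer alignment stays open. Their median log2 fold change was −0.358 in HYP and −0.475 in MeA, within what the loss of reads from 1 of 2 copies could give. In HYP 0 of these 32 calls and in MeA 2 of 21 were lower by over 2-fold, which is more than such a loss gives, but 0 of them by a further 2 SE. The median of all ZAL2 genes, however, differed from that of other genes by only 0.00462 and −0.0111. Age class as the whole cause is argued against, since with it as a covariate the lower bound of the odds ratio was 56.3 in HYP and 41 in MeA. That sequence differences between ZAL2 and ZAL2m act on the expression of their own genes is a hypothesis that was not separated from an alignment bias in favour of ZAL2m, since how ZAL2m sequence entered the alignment is not given.

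Neighbouring ZAL2 genes were called together no more often than in shuffles in HYP (7 adjacent pairs, shuffle median 7, p = 0.65) and more often in MeA (7 pairs, median 3, p = 0.033, longest run 4 genes), so no clustering shared by the regions can be stated.

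MeA libraries differed in genes of the leptomeninges, the membranes around the brain. Over a list of 15 such genes, chosen after the main axis of variation was seen and all measured in MeA, OGN ran from 1.33 to 162 CPM, MGP from 8.94 to 117 CPM and DCN from 18.8 to 137 CPM, and the mean score ran from −2.12 to 1.18. ITIH2, named above for its high fold towards MeA, is also in this list and ran from 0.286 to 57 CPM. The score was 0.15 ± 0.621 in WS (SD, n = 10) and −0.167 ± 1 in TS (n = 9), a difference of 0.318 with a 95% bootstrap interval of −0.387 to 1.07 (exact permutation test, two-sided, p = 0.42), so an unequal content between the morphs can be neither shown nor excluded. As the source of most of the MeA calls it is argued against: with the score as a covariate 54 of the 61 calls were still made, or 88.5%. The 95% interval of 77.8 to 95.3% takes the genes as independent and does not cover the spread among birds. The variation in these genes may come from membrane left on the punched sections, and no biological explanation was tested.

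Other assignments of the same libraries to the groups were drawn to see whether chance gives as many calls. Of 100 assignments with the real one included, 1 gave as many as the real 95 calls in HYP (highest other 28) and 1 as many as the 61 in MeA (highest other 2). A share of 1 in 100 is the smallest that these assignments can give, so chance is argued against for both counts and not excluded. Between the regions, with the regions exchanged in random birds, 1 of 100 gave as many as 9772 (highest other 5785, where the regions were exchanged in 4 birds and the other birds kept theirs). This is again the smallest share possible, which argues against chance and does not exclude it. Between the age classes 0 genes were called in each region, which any assignment reaches (100 of 100, highest other 2 in HYP and 18 in MeA), so this count decides nothing about chance.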
